A study of Mus musculus with 7 samples.

How the data were processed

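Total RNA from each of 7 populations of sorted C57BL6J Osr1-GFP knock-in cells was hybridised to 1 single-colour (Cy3) Agilent mouse array per population, after amplification of 10 ng of RNA with a whole-transcriptome kit, per the labels. The signal intensity of each spot was extracted by the authors with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes, and per the file headers it is the background-subtracted and detrended brightness of the spot on the linear scale, with a surrogate value for the lowest spots and no scaling between arrays. The deposited table of the series holds the same intensity: all 62976 values of each array were equal to its processed signal, and the column medians were 35.2 and 30.6 for GFP-positive and GFP-negative cells of E8.5, 45.6, 46.9 and 51.3 for gated, other GFP-positive and GFP-negative cells of E9.5, and 36.7 and 40.8 for gated and other GFP-positive cells of E11.5.

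Each array held 59305 spots that were not controls. In the same order of populations, surrogate values stood in 6014, 12590, 5236, 1661, 5710, 5106 and 5511 spots, no spot was saturated, and genes well above background numbered 20032, 16549, 20467, 23508, 20793, 20484 and 20802. Levels were log2 processed signal minus the log2 of the 75th percentile of the array, which was 253.8, 230.7, 262.4, 258.7, 300.0, 250.8 and 290.4 on the signal scale. Spots with a flag for non-uniformity or for standing apart from their replicate spots, 143, 129, 136, 127, 160, 139 and 160 per array, were left out. The spots of a probe were averaged, which left 55681 distinct probes, and a probe was well above background where a share of at least 0.5 of its spots was. Of the probes, 26425 took their gene symbol from a RefSeq table by transcript accession and 29256 the name in the array files, 19870 carried no gene name, and 27543 genes remained, 6690 of them with several probes. A gene was represented by its probe with the highest mean over the 7 arrays. In each comparison a gene counted as measured when at least 1 of the 2 arrays was well above background, and where the other was not, that side was set to the higher of its own value and the lowest well-above value of its array, so that the fold is a bound. These lowest values were at levels of -5.1, -3.46, -4.61, -4.62, -4.43, -5.12 and -5.04. A difference counted from 4-fold, and gene list members were counted from 2-fold.

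For 8 comparisons between pairs of populations, the first minus the second, the text names the 10 genes with the largest differences on each side among genes past 4-fold whose other probes, if any, did not lie more than 1 log2 unit on the opposite side. The rule and 34 gene lists of 430 symbols, of which 3 (Hbb-b1, Col6a3 and Hspa1b) matched no probe, were fixed before the data were examined, while examples from the lists, and genes outside the rule, were picked after their values were seen. The list of the 3 sort genes (Osr1, Itga8 and Pdgfra) is given gene by gene and has no median. Some genes that the rule picks are not reported here. Among genes past 4-fold, those with another probe and those whose other probe disagreed numbered 95 and 2 for E8.5 GFP-positive against GFP-negative cells, 84 and 4 for the E9.5 gate against other GFP-positive cells, 102 and 4 for the E9.5 gate against GFP-negative cells, 81 and 5 for E9.5 other GFP-positive against GFP-negative cells, 231 and 9 for the E11.5 gate against other GFP-positive cells, 118 and 7 for the E9.5 gate against E8.5 GFP-positive cells, 145 and 9 for the 2 gates across stages, and 238 and 11 for the other GFP-positive cells across stages. Random lists, 10000 per list and comparison with seed 1, were drawn within 10 bins of expression.

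With 1 array per population no test between groups could be run, and the number of arrays limits the precision. The 399 probes spotted 10 times on each array gave a median standard deviation of 0.11 within an array on the log2 scale, or 0.15 for a difference, which covers spot noise alone and was chosen as the measure of a moved value after the data were examined. Pearson correlations between arrays ran from 0.924 to 0.97. The slide number in the files split the arrays 5 to 2, with the gated and GFP-negative arrays of E9.5 on the second slide, so 4 comparisons lay within a slide and 4 across slides.

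The steps from gene levels to differences, bounds and list percentiles were tested on simulated data in which 200 of 27543 genes were changed. Both simulated arrays of a comparison came from the levels of its second array with spot noise alone, and the changed genes were clear of background. Scaling, averaging of spots and choice of probe were not simulated, nor was any error from slide, sort or embryo. Of genes changed by 3 log2 units, 100.0% were recovered in every comparison except that of the 2 gates across stages, with 98.75%. At 4 log2 units the recovered share was 100.0%, save for E9.5 other GFP-positive against GFP-negative cells (98.75%), the 2 gates across stages (96.25%) and the other GFP-positive cells across stages (97.5%). No gene changed by 1 log2 unit was called, and of the unchanged genes 0, 0, 0, 1, 1, 10, 1 and 2 were called, in the order in which the 8 comparisons are listed for the probes.

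The alternatives were normexp background correction of the spot and background intensity (offset 50), quantile normalization, median centring, genes above background on both arrays alone, no filter, the median over the probes of a gene, a 2-fold threshold, and the deposited table without scaling. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, figures matplotlib 3.10.9, and normexp limma 3.58.1 in R 4.3.3. Probe coordinates are those printed in the array files, mm9 (NCBI37). Probes for long intergenic RNA were not used in the comparisons of genes, and no array of GFP-negative cells of E11.5 was analysed here.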

Results

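Cells of mouse embryos carrying an Osr1-GFP knock-in were sorted and their RNA was measured on single-colour microarrays. Green fluorescent protein (GFP) marks cells that express Osr1, a transcription factor of the early intermediate and lateral plate mesoderm. The 7 sorted populations had 1 array each, so there were no replicates and no test could be run. Each fold is the difference between 2 arrays with an unknown spread between embryos and sorts. At E8.5, GFP-positive and GFP-negative cells came from the whole embryo. At E9.5, 3 populations came from the caudal part of the embryo: gated cells (GFP-positive, with the integrin Itga8 on the surface and without the receptor Pdgfra), the other GFP-positive cells, and GFP-negative cells. At E11.5, gated and other GFP-positive cells came from the metanephric mesenchyme, the tissue that gives rise to nephrons and renal stroma. The share of spots well above background was 70.3% and 56.2% on the GFP-positive and GFP-negative E8.5 arrays. It was 72.4%, 84.1% and 73.8% on the gated, other GFP-positive and GFP-negative E9.5 arrays and 72.7% and 74.0% on the gated and other GFP-positive E11.5 arrays. A level is the log2 signal minus the 75th percentile of its array, and "at least" marks a fold in which the dimmer side was not well above background and was set at its bound. A gene list is described by the number of measured members at least 2-fold higher or lower, and its median log2 difference. The percentile of that median among 10000 random lists of matched expression is given as a description of these arrays. Some lists hold genes on which the cells were sorted, and these are counted in every comparison: Osr1 and Itga8 among nephron progenitor genes, Osr1 among early intermediate mesoderm genes and Pdgfra among stromal genes. Lists also share members, so their counts are not independent. Krt8, Krt18, Krt19 and Epcam are in both the endoderm and surface ectoderm lists, and Sp5, T and Cdx1 in both the posterior axial and Wnt lists.

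The sorted genes were checked first. Osr1 stood at levels of 0.85, 1.03, -0.08, 1.63 and -1.80 on the 5 GFP-positive arrays and was not well above background on the GFP-negative arrays of E8.5 and E9.5, where its signals were -3.23 and -4.38. Itga8 reached 2.15 in gated against 0.20 in other GFP-positive cells at E9.5, and 2.82 against -1.31 at E11.5. Pdgfra stood at -0.52 against 3.44 at E9.5, and at E11.5 it was not well above background in the gate, with a signal of -5.92, against 4.04 in the other cells. In the mm9 (NCBI37) coordinates of the array, the probe for Osr1 lies on chromosome 12 from 9587390 to 9587449, and that for Pdgfra on chromosome 5 from 75593888 to 75593947. Probes for the kidney transcription factors lie for Six2 on chromosome 17 from 86083634 to 86083693, for Wt1 on chromosome 2 from 105013656 to 105013715 and for Pax2 on chromosome 19 from 44909895 to 44909954.

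**Figure D1:**
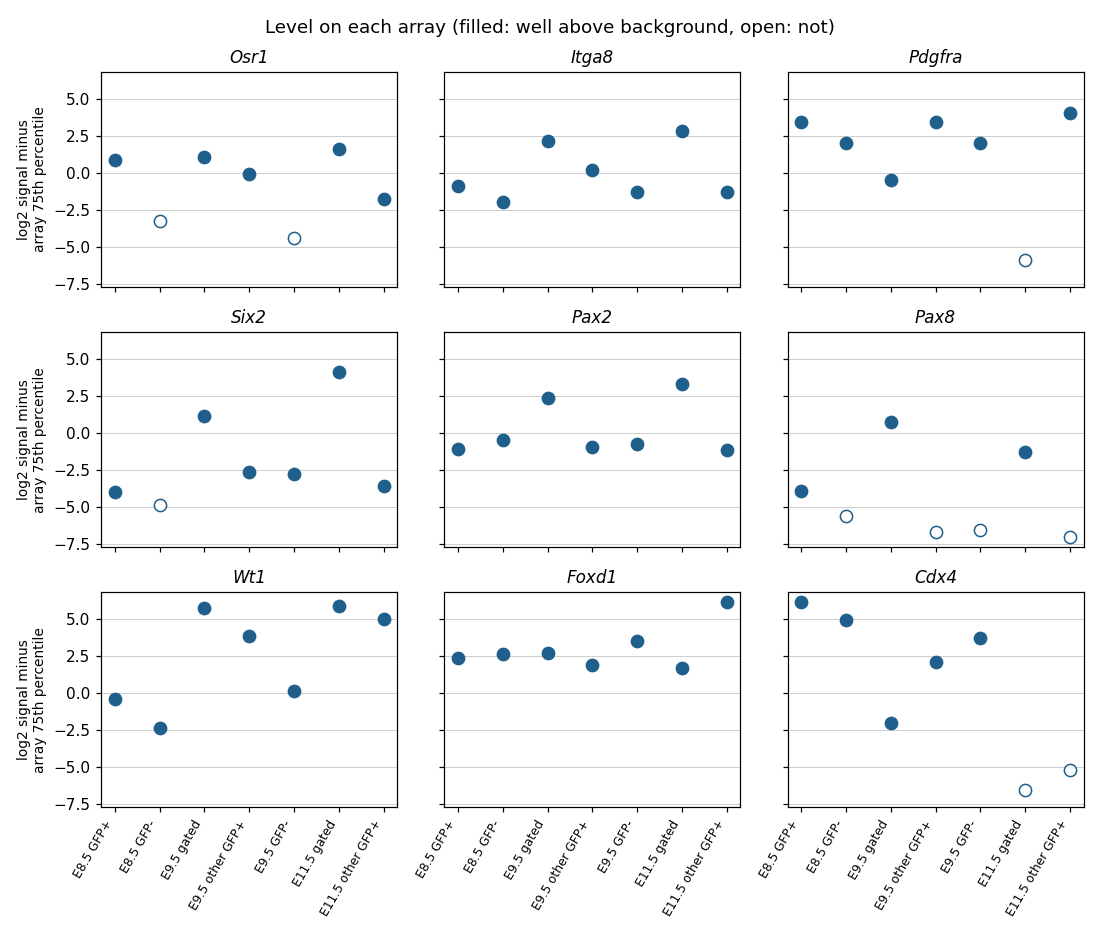
Level of 9 genes on each of the 7 arrays (y axis, log2 signal minus the 75th percentile of the array; filled points are well above background, open points are not). Six2, Pax2 and Pax8 are highest on the gated arrays, Foxd1 stands at 6.14 in the other GFP-positive cells at E11.5, and Cdx4 is highest at E8.5.

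At E9.5 the gated cells were set against the other GFP-positive cells because the study sought what sets nephron progenitors apart from nearby mesenchyme. The other GFP-positive cells are defined by lying outside the gate alone, and their array held transcripts of further tissues. Transcription factors of the early kidney were higher in the gate: Pax8 by at least 40.7-fold and Pax2 by 9.82-fold, which together are needed for kidney formation. Six2, which keeps nephron progenitors undifferentiated, was higher by 13.8-fold and the podocyte and progenitor factor Wt1 by 3.72-fold. Gdnf, the growth factor that draws out the ureteric bud, was 9.57-fold higher, its receptor subunit Gfra1 8.88-fold, and the fibroblast growth factors Fgf20 and Fgf9, which maintain nephron progenitors, 9.52-fold and 4.64-fold. Of the 25 measured metanephric nephron progenitor genes, 12 were at least 2-fold higher and 2 lower, these being Hoxd11 and Cited1 at log2 differences of -3.27 and -1.28 (list median 0.81, percentile 100). Of the higher ones, Osr1 (log2 difference 1.11) and Itga8 (1.95) follow from the sort. Early intermediate mesoderm genes had 8 of 13 higher and 0 lower, Foxc2 by 2.89-fold and Emx2 by 2.18-fold among them (median 1.10, percentile 100). Among the named genes with the highest differences were also Clec10a, a lectin receptor (39.9-fold), with Matn1, a cartilage matrix protein (at least 30.8-fold), Klhl14 (22.8-fold), Eva1a (at least 21.5-fold), and Plet1 (18.8-fold). The Notch target Heyl (at least 18.3-fold), the alcohol dehydrogenase Adh1 (17.8-fold) and the actinin Actn3 (at least 17-fold) were in this group too.

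Some mesenchymal and lateral plate genes were lower in the E9.5 gate, while many members of both lists lay within 2-fold. In the stromal list 8 of 18 members were lower and 1 higher (median -0.81, percentile 0.0). The mesenchymal transcription factors Prrx1, Twist1 and Tbx18 were lower by 8.58-fold, 8.34-fold and 5.66-fold, and Pdgfra, on which the cells were sorted, by 15.5-fold. The limb and heart factors Hand2, Tbx5 and Tbx4 were lower by at least 32.9-fold, at least 30-fold and 12.3-fold, and 7 of 18 lateral plate and heart genes were lower, 1 higher and 10 within 2-fold (median -0.40, percentile 1.0). Epha3, an ephrin receptor, and the T-box gene Tbx15 were each 33-fold lower, and the Notch ligand Dll3 at least 27.8-fold. Posterior Hox genes followed the same side, with 4 of 7 members of groups 11 to 13 lower and 0 higher, among them Hoxd13 by 16.8-fold (median -1.38). Transcripts of tissues outside the kidney field also stood lower in the gate: 11 of 17 endoderm genes, with Foxa2 by at least 33.8-fold and Foxa1 by at least 15.5-fold (median -1.41). The same held for 8 of 14 surface ectoderm genes, with Tfap2c at 22.8-fold (median -1.05). The embryonic globins Hbb-y and Hbb-bh1 were at least 65.8-fold and 39.8-fold lower and the globin Hba-a2 24.8-fold. The blood list had 5 of 17 lower and 3 higher, the latter being Alas2 (2.82-fold), Tal1 (2.82-fold) and Lmo2 (2.85-fold), and its median of -0.51 (percentile 0.7) became 0.08 over genes above background on both arrays. In the endothelial list 8 of 18 genes were higher, such as Cldn5 (5.0-fold) and Sox17 (4.36-fold), and Erg alone was lower by 6.09-fold (median 0.75). In all, 23907 genes were measured, of which 204 were at least 4-fold higher and 282 lower, 61 and 142 of them as bounds. Quantile normalization gave 446 and 308 and genes above background on both arrays 143 and 140, so the larger side turned, and the median over all genes was -0.15 against -0.04 under that scaling. The 2 arrays lay on different slides, so slide and population cannot be told apart here.

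At E11.5 the same gate was set against the other GFP-positive cells of the metanephric mesenchyme. Six2 was 205.3-fold higher in the gate, Pax2 21.7-fold, Pax8 at least 13.2-fold, Fgf20 at least 53-fold, Fgf9 at least 31.5-fold, Gfra1 at least 37.1-fold and Cited1, a transcriptional co-regulator of uncommitted progenitors, 34.4-fold. Crym, a thyroid hormone binding protein, was at least 357.5-fold higher. In total 15 of the 25 nephron progenitor genes were higher against 2 lower, among these Hoxc11 by at least 3.03-fold (median 2.19, percentile 100). Early intermediate mesoderm genes had 3 of 12 higher and 3 lower at this stage (median 0.13, percentile 43.7). The lower ones were Gata3 by at least 17.3-fold, Emx2 by at least 3.36-fold and Foxc1 by 2.26-fold. Others among the highest named genes were the chemokine receptor Cxcr4 (194.4-fold), Clec10a (at least 152.5-fold), the peptidylarginine deiminase Padi2 (148.3-fold) and the adaptor Grb7 (at least 102.0-fold). Next came the phosphoinositide 3-kinase subunit Pik3r5 (at least 82.9-fold), the nuclear pore protein Nup210 (66-fold) and Rspo1, a secreted enhancer of Wnt signalling (64.3-fold). Targets of fibroblast growth factor signalling were higher in 6 of 12 cases and lower in 0, with Dusp4 at 7.37-fold, Etv4 at 6.22-fold and Etv5 at 3.66-fold (median 1.03, percentile 100). Npnt, the matrix ligand of the integrin that contains Itga8, was at least 24-fold higher.

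Stromal genes were lower in the E11.5 gate almost throughout: 16 of 18 were lower, 0 higher, and Meis2 and Tcf21 lay within 2-fold (median -2.81, percentile 0.0). Foxd1, the marker of renal stromal progenitors, was 21.9-fold lower and Tbx18, a factor of the ureteric mesenchyme, at least 170.2-fold. Also lower were Twist1 by at least 128.5-fold, the pericyte receptor Pdgfrb at 22.2-fold, the stromal factor Ebf3 at 55.5-fold and Pdgfra by at least 572.6-fold. Fibrillar collagens of connective tissue were lower too, Col1a2 by 148.5-fold, Col1a1 by 96.5-fold and Col3a1 by 54.1-fold. In their list 11 of 17 extracellular matrix genes were lower against 1 higher, the tenascin Tnc by at least 4.84-fold (median -2.13). The lowest named genes further held the sphingosine phosphate receptor S1pr3 (446.1-fold), Tbx1 (at least 353.3-fold), Brinp1 (at least 280.6-fold) and Prdm16 (at least 187.6-fold). They were followed by the pericyte gene Rgs5 (169.9-fold), and the adhesion molecules Vcam1 (at least 162.3-fold) and Cntn1 (at least 159.9-fold). Lateral plate and heart genes had 7 of 12 lower and 1 higher, with Gata6 lower by 38.8-fold and Isl1 by 24.3-fold (median -1.23). Genes of retinoic acid response and metabolism had 6 of 12 lower and 0 higher, with the binding protein Crabp1 at 14-fold and the retinaldehyde reductase Dhrs3 at 3.76-fold (median -0.69). Beside these groups, immediate early genes, which tissue dissociation can induce, were lower in 8 of 12 cases and higher in 2, with Dusp1 lower by 3.96-fold and Fos by 3.78-fold (median -1.25). Cell cycle genes had 4 of 21 higher, Mcm2 by 3.23-fold, and 0 lower (median 0.55), and 2 of 14 housekeeping genes were higher and 1 lower (median 0.46). Of 21939 measured genes, 475 were at least 4-fold higher and 714 lower, 163 and 333 as bounds. The median over all genes was 0.15, 0.05 under quantile normalization and -0.06 in the unscaled value table, where 379 genes were higher and 885 lower. The larger side turned at 2-fold, with 2321 higher and 2073 lower, and without filter or bound, with 1028 and 936.

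Both gate comparisons were set side by side over the 21360 genes measured in each. Of the 178 genes higher at E9.5 and the 440 higher at E11.5, 56 were shared, against 3.67 for independent draws. They held Six2, Pax2, Pax8, Crym, Gdnf, Gfra1, Fgf9, Fgf20, Heyl and the endocytic receptor Lrp2. Of the 228 lower at E9.5 and 654 lower at E11.5, 60 were shared, against 6.98. Twist1, Tbx18, Gata6, Isl1, Col1a1, Col3a1, Crabp1, Evx1 and Hoxd13 were among them, as was Pdgfra, which follows from the sort. Genes on opposite sides also exceeded independent draws, with 10 against 5.45 for higher at E9.5 and lower at E11.5. The other way round there were 14 against 4.7. The shared counts were 13 and 10 with normexp, against 0.237 and 0.332 for independent draws, and 26 and 20 over genes above background on both arrays, against 1.57 and 1.79. Without filter or bound they were 79 and 114, against 12.2 and 37.1, and at 2-fold 291 and 410, against 110 and 153.0. Across genes, which are not independent replicates, the Pearson correlation of the differences was 0.13 and the Spearman correlation -0.0.

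**Figure D2:**
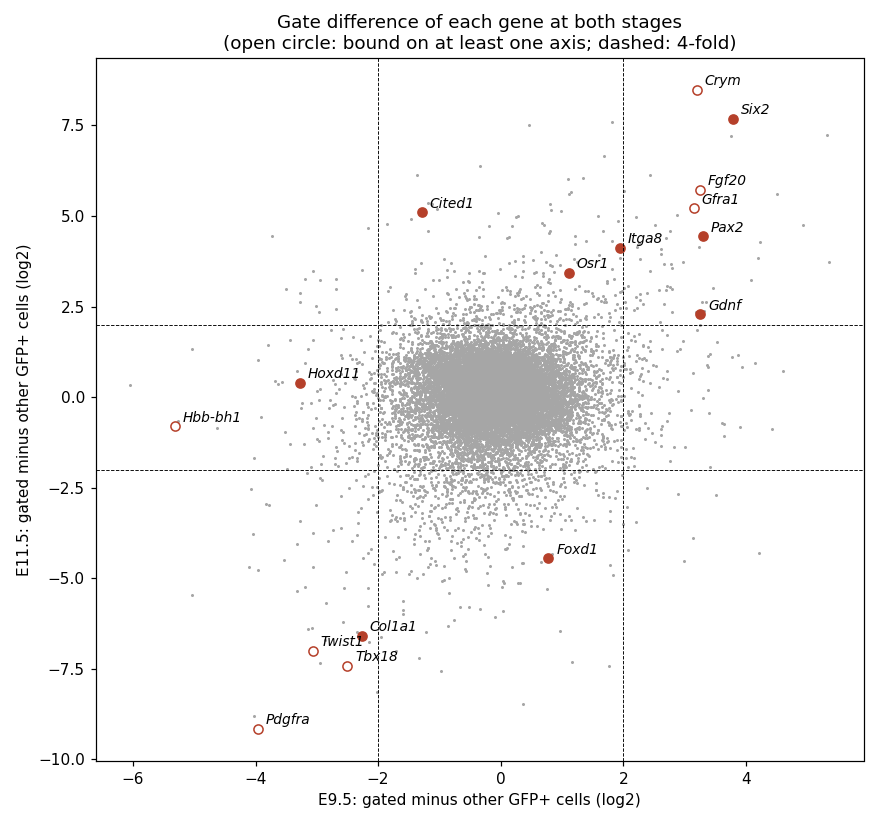
Log2 difference between gated and other GFP-positive cells at E9.5 (x axis) and E11.5 (y axis), 1 point per gene measured at both stages, with dashed lines at 4-fold and open circles where a named gene is a bound. Six2 lies at 3.79 and 7.68 and Pdgfra, on which the cells were sorted, at -3.96 and, as a bound, -9.16.

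At E8.5 the GFP-positive cells were set against the GFP-negative cells to describe the earliest precursors. Mesodermal regulators were higher in the GFP-positive cells: Osr1 by at least 16.9-fold, the mesenchymal homeobox gene Alx1 by at least 15.3-fold and Isl1, a factor of heart and hindlimb progenitors, by 13.3-fold. Etv2, which starts the endothelial and blood programme, was 13.6-fold higher. Of 18 lateral plate and heart genes, 16 were higher and 0 lower, with Prrx1 at 9.31-fold, Gata6 at 7.3-fold and Hand2 at 6.81-fold (median 1.89, percentile 100). In the nephron progenitor list 13 of 21 were higher and 0 lower, such as Fgf9 (4.67-fold) and Hoxc10 (4.12-fold) (median 1.04). Hoxd11, counted as higher here and in Hox groups 11 to 13 at a log2 difference of 1.04, had another probe that disagreed in sign. Pax2 stood at a log2 difference of -0.61 and Six2 at levels of -3.97 and -4.85, the second not well above background. Every Hox list had more members higher than lower in the GFP-positive cells: 8 of 12 in groups 1 to 4, led by Hoxd1 at 12.6-fold, and 7 of 11 in groups 5 to 8 (medians 1.25 and 1.30). The higher genes were 6 of 7 in groups 9 and 10, led by Hoxd9 at 7.46-fold, and 4 of 7 in groups 11 to 13 (medians 1.68 and 1.01), and no member of the 4 lists was lower. Target genes of Bmp signalling had 7 of 10 higher, Msx2 by 3.57-fold (median 1.44). Those of Wnt signalling had 6 of 13, Lef1 by 10.5-fold and Axin2 by 2.84-fold, and those of retinoic acid 6 of 12, the receptor Rara by 5.17-fold (medians 1.0 and 1.08). No member of these 3 lists was lower. Endothelial genes had 9 of 18 higher and 0 lower, Sox7 by 4.56-fold and Flt1 by 4.38-fold (median 0.94). Rspo1 (at least 11.3-fold), the tight junction gene Cldn11 (10.1-fold), Gas7 (at least 9.64-fold) and the neurotrophin receptor Ngfr (9.46-fold) completed the 10 highest named genes. Red blood cell genes were lower in the GFP-positive cells, 14 of 17 in the blood list against 0 higher (median -6.54, percentile 0.0). Inside and outside that list, the globins Hba-x stood 1022.1-fold lower, Hbb-y 840.2-fold, Hba-a1 552.1-fold, Hbb-bt at least 435.8-fold and Hba-a2 428.3-fold. So did the erythroid factor Gata1 by at least 813.4-fold, the anion exchanger Slc4a1 at 297.8-fold and the globin chaperone Ahsp at 285.8-fold. Aasdh, an aminoadipate semialdehyde dehydrogenase, was 872.8-fold lower, and its level of 9.34 on the GFP-negative E8.5 array stood apart from levels between -0.52 and 0.55 on the other 6 arrays. The neural list had 3 of 14 lower, with Sox2 and Sox3 at 13.6-fold and 12.1-fold, 1 higher and 10 within 2-fold (median -0.08, percentile 22.5). Of 18295 measured genes, 181 were at least 4-fold higher and 495 lower, 73 and 243 as bounds. At 2-fold the larger side turned, with 1423 higher and 1244 lower. The median over all genes was 0.05 and became 0.17 in the unscaled value table, and 56.2% of spots were well above background on the GFP-negative array against 70.3% on the other.

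Gated cells of E9.5 were also set against the GFP-negative cells of the same region. Highest in the gate were Crym (106.6-fold), the neurotensin receptor Ntsr1 (at least 104.2-fold), Clec10a (at least 74-fold), Adh1 (55.9-fold) and Wt1 (48.3-fold). They were followed by Osr1 (at least 42.5-fold), Plet1 (41.9-fold), Pax8 (at least 35.7-fold) and the collectin Colec10 (at least 24.2-fold). Nephron progenitor genes had 12 of 25 higher and 4 lower, the lower ones being Hoxd11, Cited1, Cdh6 and Spock2 at log2 differences of -2.13, -1.44, -1.68 and -1.39 (median 0.99, percentile 100). Endothelial genes had 12 of 18 higher and 0 lower, with Etv2 at 17.4-fold and Sox17 at 10.6-fold (median 1.30). Genes of posterior axial progenitors and presomitic mesoderm, the growing tail end of the embryo, were lower in 16 of 21 cases and higher in 0 (median -2.24, percentile 0.0). Cdx4 was lower by 54.1-fold, Dll3 by at least 110.1-fold and T, the marker of the tail bud and notochord, by at least 12.4-fold. Neural genes were lower in 16 of 20 cases, Sox2 by at least 153.1-fold, Sox3 by 47.1-fold and the neuronal tubulin Tubb3 by 27.8-fold, and 1 was higher (median -1.75). Neural crest genes had 6 of 10 lower and 0 higher, Tfap2b by 59.6-fold (median -1.80). The sclerotome factor Pax1, the roof plate factor Lmx1a and Foxa2 were at least 262.3-fold, 180.9-fold and at least 155.0-fold lower. Blood genes had 12 of 17 lower and 0 higher, Hbb-y by at least 7450.3-fold, Hbb-bh1 by 4708.9-fold, Hba-x by at least 2406.5-fold and Hba-a1 by 537.3-fold (median -2.56). The globins Hba-a2 and Hbb-bt outside that list were 1918.3-fold and at least 276.1-fold lower. Lamtor1, an endosomal scaffold protein, was 40.6-fold higher, and its level of -1.43 on the GFP-negative E9.5 array stood apart from levels between 3.81 and 4.29 on the other 6. Of 21764 measured genes, 261 were at least 4-fold higher and 406 lower, 97 and 190 as bounds. The unscaled value table gave 199 and 513, and there the median over all genes was -0.18 in place of 0.01.

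The remaining E9.5 comparison set the other GFP-positive cells against the GFP-negative cells. Among the 10 highest named genes were the hindlimb factors Tbx4 (51.1-fold) and Pitx1 (29.7-fold) and the homeobox gene Alx1 (26.9-fold). Lateral plate and heart genes had 10 of 18 higher and 2 lower, with Gata6 higher by 13.2-fold, Tbx5 by 11.1-fold and Hand2 by 10.6-fold (median 1.48, percentile 100). Stromal genes had 6 of 18 higher and 3 lower, with Prrx1 at 10.8-fold (median 0.79). Nephron progenitor genes had 8 of 25 higher and 2 lower, with Wt1 at 13-fold and Crym at 11.6-fold (median 0.36). The others of the 10 were Lamtor1 (48.2-fold), the monoamine transporter Slc18a1 (at least 31.1-fold), Colec10 (at least 24.4-fold), Osr1 (at least 19.7-fold), the endothelial factor Erg (19.4-fold), the calpain Capn6 (18.6-fold) and Jaml (at least 16-fold). Lower were 13 of 21 posterior axial genes, 15 of 20 neural genes, 6 of 10 neural crest genes and 11 of 18 blood genes, with 0 higher in each of the 4 lists (medians -1.61, -1.90, -1.94 and -1.96). Genes of these kinds included Sox2 (at least 154.3-fold), the neural factor Prdm8 (at least 156.0-fold), the Notch modulator Lfng (17.4-fold), Tfap2b (24.4-fold), Hbb-bt (at least 278.2-fold) and Hba-x (201.7-fold). Lower in the same way were Hba-a1 (138.3-fold), Hbb-bh1 (118.4-fold), Hbb-y (113.2-fold), Ahsp (at least 111.2-fold), and Slc4a1 (94.9-fold). Of 24075 measured genes, 191 were at least 4-fold higher and 302 lower, 84 and 76 as bounds. The split was 194 to 570 under quantile normalization, 133 to 390 in the unscaled value table and 36 to 99 with normexp. It turned round at 2-fold, to 2063 higher and 1247 lower, and without filter or bound, to 1496 and 442. The median over all genes moved from 0.14 to 0.03 under quantile normalization and -0.08 in the value table, and slide and population cannot be told apart.

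Across stages, gated cells of E9.5 were set against the GFP-positive cells of E8.5, which had not been gated and came from the whole embryo. Kidney genes stood higher at E9.5: Wt1 by 70.4-fold, Six2 by 35.1-fold, Fgf20 by at least 35.7-fold, Pax8 by 25.5-fold, Gfra1 by at least 20-fold and Gdnf by at least 19.1-fold. Nephron progenitor genes had 12 of 25 higher and 1 lower, Cited1 by 21.7-fold (median 0.68, percentile 100). Hox groups 9 and 10 had 4 of 7 higher and 0 lower, with Hoxc10 at 8.79-fold (median 1.19). Adh1 (123.9-fold), Clec10a (at least 117.3-fold), the mitochondrial co-activator Ppargc1a (46.5-fold), Matn1 (at least 42.9-fold), Ntsr1 (33.6-fold) and Eya4 (at least 31.7-fold) were other named genes on the higher side. Posterior axial genes were lower in 17 of 21 cases and higher in 0, Cdx4 by 289.5-fold, Cdx2 by at least 75.9-fold, Evx1 by 74.3-fold and Dll3 by at least 71.8-fold (median -2.66, percentile 0.0). Endoderm genes had 12 of 17 lower and 0 higher, Foxa2 by at least 44.5-fold and the keratin Krt8 by 10.3-fold (median -2.80). Lateral plate and heart genes had 12 of 18 lower, Hand2 by at least 30.9-fold and Tbx4 by 29.5-fold, against 1 higher, Wt1 (median -1.63). Wnt targets had 9 of 13 lower and 0 higher, Sp5 by 7.58-fold and Axin2 by 4.69-fold (median -1.60). Further named genes on the lower side were Tex19.1, a germ cell and placenta gene (at least 83.3-fold), the secreted antagonist Cer1 (at least 54.9-fold), Hbb-bh1 (41.4-fold) and the imprinted gene Phlda2 (38.5-fold). Beside these groups, immediate early genes had 5 of 12 higher and 1 lower, with Fos higher by 4.2-fold and Egr1 by 4.08-fold (median 0.71, percentile 99.7). Of 21636 measured genes, 525 were at least 4-fold higher and 341 lower, 291 and 145 as bounds. Quantile normalization gave 368 and 436 and normexp 75 and 94, so the larger side differed between scalings. The arrays lay on different slides, so slide, stage, gating and region cannot be told apart.

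Between E9.5 and E11.5, gated cells were set against gated cells. Posterior Hox genes, of which those of group 11 are needed for kidney induction, stood higher at E11.5, Hoxd11 by 36.6-fold, Hoxd12 by 9.52-fold and Hoxa11 by 6.11-fold. These were the 3 higher ones of 5 measured genes of groups 11 to 13, and Hoxd13 was lower by 2.72-fold (median 2.61). Six2 was 7.66-fold higher, the signalling adaptor Traf1 11.4-fold and the proteoglycan Spock2 28.1-fold. Nephron progenitor genes had 7 of 24 higher and 2 lower, among these Fgf9 by 2.79-fold (median 0.60, percentile 100). Endothelial genes were lower at E11.5 in 14 of 18 cases and higher in 0, with the cadherin Cdh5 by at least 43.1-fold, Sox17 by at least 24.6-fold and Etv2 at 18.8-fold (median -2.90, percentile 0.0). Stromal genes had 9 of 17 lower and 2 higher, with Twist1 lower by at least 27-fold and Pdgfra by at least 24.2-fold (median -1.27). Lateral plate and heart genes had 11 of 16 lower, the cardiac actin Actc1 by at least 57.8-fold (median -1.55). Extracellular matrix genes had 8 of 16 lower and 2 higher, with the proteoglycan Lum lower by at least 33.1-fold (median -1.08). Wnt targets had 7 of 11 lower and 0 higher, Dkk1 by at least 14.5-fold (median -1.40). Highest of the named genes were Moxd1 (at least 71.5-fold), Sorcs3 (at least 50.9-fold), the adhesion molecule Ncam2 (at least 33.3-fold) and Caps2 (at least 30.7-fold). They were joined by Pik3r5 (30.3-fold), Slc25a21 (26-fold), the growth factor Fgf1 (24.3-fold) and the protease Mcpt8 (at least 24-fold). Lowest were Xist, the RNA that silences an X chromosome in female cells (at least 226.4-fold), the matrix link protein Hapln1 (at least 104.4-fold), the mesenchymal factor Foxf2 (at least 69.6-fold) and Gimap8 (at least 50.5-fold). Others were the protease Plau (at least 49.9-fold), Ctla2a (at least 49.7-fold), Ahnak (at least 48.7-fold), the myelin protein gene Pmp22 (at least 43.7-fold) and Asb4 (43.6-fold). Immediate early genes had 4 of 12 higher and 1 lower here, with Egr1 higher by 5.11-fold (median 0.45, percentile 99.3). Of 21792 measured genes, 277 were at least 4-fold higher and 655 lower, 96 and 366 as bounds. Quantile normalization gave 348 and 514 and normexp 73 and 97. The E9.5 cells came from the caudal part of the embryo and the E11.5 cells from the metanephric mesenchyme. Slide, stage and dissected region therefore cannot be told apart in this pair. Neither can the sex of the embryos, which may differ given Xist.

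The other GFP-positive cells of E11.5, from the metanephric mesenchyme, were set against those of E9.5, from the caudal part of the embryo. Stromal genes stood higher at E11.5 in 9 of 18 cases and lower in 0 (median 1.17, percentile 100, where all genes had a median of -0.36). Foxd1 was higher by 19.1-fold, the secreted protein gene Fibin by 6.95-fold, Tbx18 by 5.44-fold and Ebf3 by 4.8-fold. Extracellular matrix genes had 7 of 17 higher and 2 lower, with the elastin gene Eln higher by 5.67-fold and Col1a1 by 4.67-fold (median 0.91). Highest of the named genes at E11.5 were Cntn1 (at least 92.2-fold), Nav3 (70.9-fold), Stmn2 (69.2-fold) and Chl1 (68-fold). Ncam2 was 47.3-fold higher by its brightest probe, though -0.68 on the log2 scale as the median of its probes. Gpm6b (36.3-fold), Clstn2 (35.9-fold), the transcription factor Nfib (50.7-fold) and Fam155a (36.1-fold) followed. The neural list, which holds Stmn2, had 3 of 16 higher and 5 lower, and basement membrane and cell adhesion genes had 2 of 19 higher and 8 lower (median -0.72, percentile 0.1). Lower at E11.5 were 15 of 17 endoderm genes, with Foxa2 by at least 61.9-fold (median -2.41). So were 10 of 14 surface ectoderm genes, Tfap2c by at least 80.8-fold, and 11 of 19 posterior axial genes, Cdx4 by at least 142.9-fold, with none higher in the 3 lists (medians -1.98 and -1.80). Endothelial genes had 11 of 18 lower and 1, Fli1, higher by 2.78-fold, with Erg lower by at least 75.7-fold (median -1.30). Tbx4 (at least 128.4-fold) and Tbx15 (at least 90.8-fold), the limb factor Lhx2 (92-fold), the desmosomal gene Dsp (at least 110.6-fold), the dynein subunit Dync1i1 (96.2-fold), Hbb-bh1 (95.3-fold) and Xist (at least 173.1-fold) were the remaining lowest genes. Beside these groups, immediate early genes were higher at E11.5 in 8 of 12 cases and lower in 2, with Fosb higher by 13.2-fold, Fos by 9.78-fold and Egr1 by 9.03-fold (median 2.23, percentile 100). Glycolysis and hypoxia genes were lower in 8 of 14 and higher in 1 (median -1.05). Cell cycle genes were lower in 7 of 21 and higher in 0, Mcm2 by 3.45-fold (median -0.80). Housekeeping genes were also lower in 3 of 14 and higher in 1 (median -0.50), beside the median of -0.36 over all genes. Of 23992 measured genes, 386 were at least 4-fold higher and 820 lower, 69 and 460 as bounds. The split was 751 to 420 under quantile normalization, 475 to 601 in the unscaled value table and 130 to 138 with normexp. The median over all genes moved from -0.36 to -0.04, -0.2 and -0.22, so no statement about the balance of higher and lower genes holds for this pair. Stage and dissected region cannot be told apart in it, and neither can the sex of the embryos, which may differ given Xist.

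**Figure D3:**
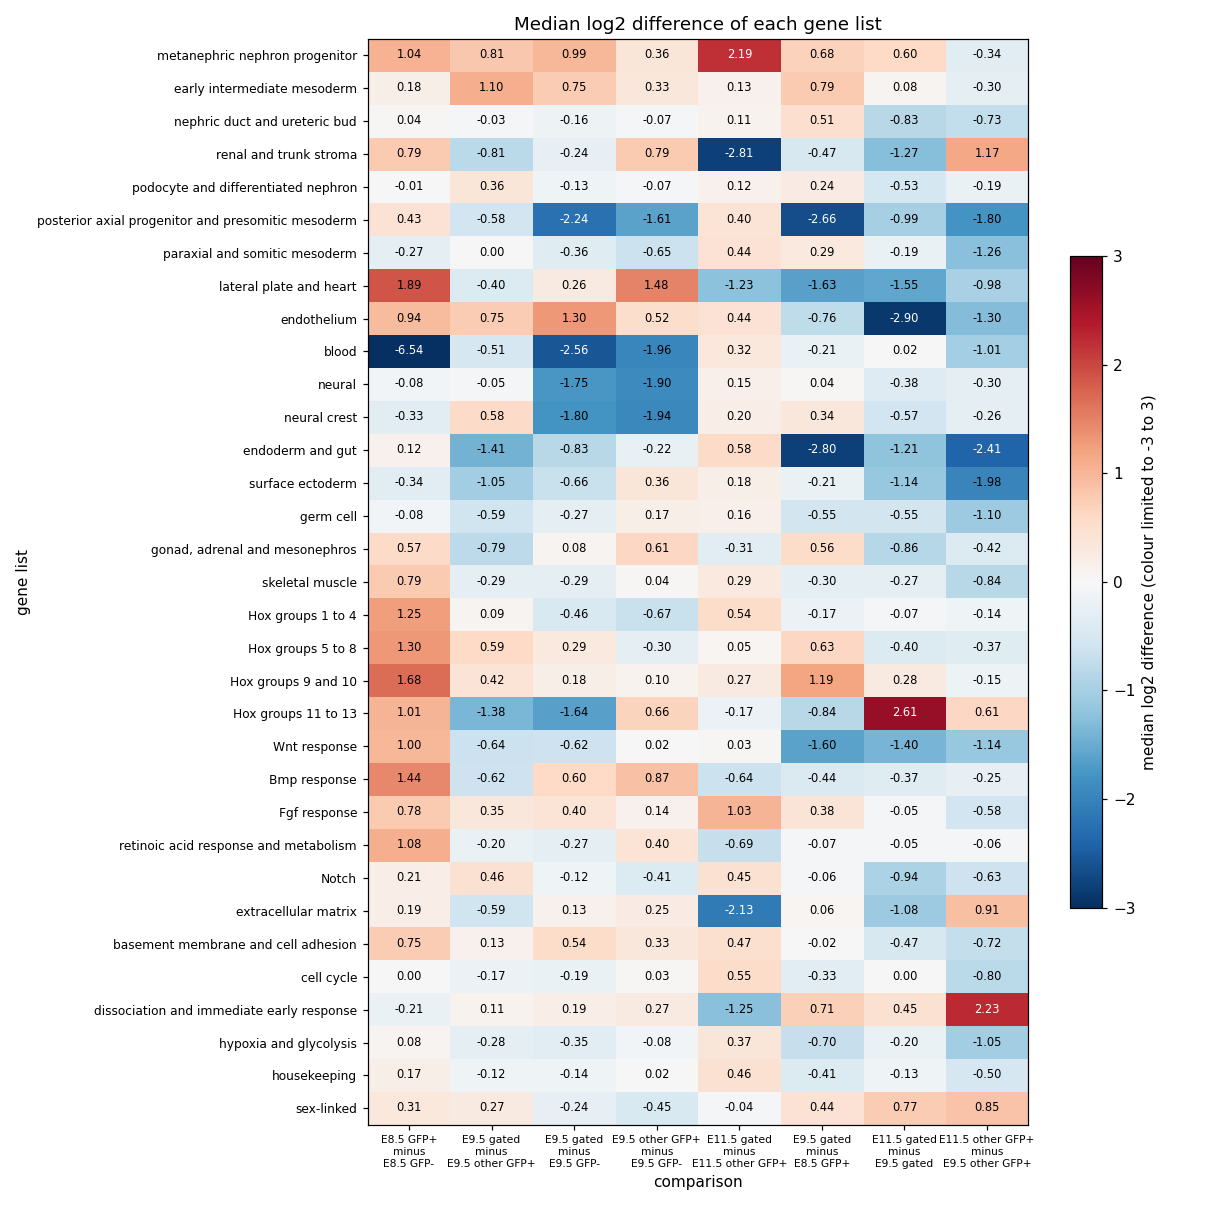
Median log2 difference of each gene list (y axis) in the 8 comparisons (x axis, first minus second population), printed in each cell, with the colour scale limited to -3 to 3. Stromal genes stand at -2.81 and nephron progenitor genes at 2.19 in the E11.5 gate. None of the 55 medians of at least 2-fold changed sign under any alternative that recomputed them, but with normexp only 24 medians were of that size.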

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

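Both tests of the slide were fixed before their values were seen, although single gene differences of both gate comparisons had been looked at.

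Some genes stood on opposite sides of the gate at the 2 stages: 10 genes were at least 4-fold higher in the gate at E9.5 and 4-fold lower at E11.5, and 14 the other way round, against 5.45 and 4.7 for independent draws. The protease Plau was at 2.99 at E9.5 and -4.51 at E11.5 on the log2 scale, the E11.5 value being a bound. In the other direction the monoamine transporter Slc18a1 was at -2.16 and, as a bound, 4.68. The dynein subunit Dync1i1 was at -2.27 and 3.5, both measured. Pou3f1, a factor of early epiblast and neural cells, was among the 10, and Adamts17 was among the 14, genes singled out after their values were seen. The difference between the stages was not tested, since each stage has 1 array per population.

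Probes for long intergenic RNA, which the comparisons of genes leave out, also passed 4-fold. Of 13767 measured probes at E9.5, 140 were higher in the gate and 109 lower, 1.81% against 2.03% of named genes. At E11.5, 249 were higher and 274 lower of 12497 measured, 4.19% against 5.42%.

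At E9.5 the gated array lay on the second slide and the other GFP-positive array on the first, so the 4-fold differences between them might come from the slide or scan. Genes higher in that comparison had a median of 0.98 at E11.5, where both arrays share a slide, and genes lower there -0.8, a gap of 1.77. Of the 178 and 228 genes, 88 and 98 were at least 2-fold the same way and 27 and 35 the opposite way. Both medians lay outside the range set in advance for a slide cause, but they and the gap fell short of the values set against it. The test therefore stays undecided, and slide and population cannot be told apart for these differences as a set. A shift shared by both arrays of the second slide was sought among genes at least 2-fold above or below all other arrays. That pair was at rank 7 of 21 pairs, with 15 of 15635 genes, against 139 for the E11.5 pair. The rank lay outside those set in advance for such a shift, which argues against a shared 2-fold shift of many genes. Paired with the other GFP-positive E9.5 array, on the first slide, each of them had 6 such genes. A smaller shift, or one of few genes, therefore cannot be excluded. The sorted population, the biological difference of the design, stays open beside the slide.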

How the results depend on the processing

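All alternatives were fixed before the data were examined, and only the spread by which a value counted as moved, 0.15 on the log2 scale, was chosen after. Counts of genes past 4-fold follow in 1 order: E8.5 GFP-positive against GFP-negative, E9.5 gate against other GFP-positive, E9.5 gate against GFP-negative, E9.5 other GFP-positive against GFP-negative, E11.5 gate against other GFP-positive, E9.5 gate against E8.5 GFP-positive, gate across stages and other GFP-positive across stages. As reported they were 676, 486, 667, 493, 1189, 866, 932 and 1206. Normexp correction gave 170, 91, 179, 135, 322, 169, 170 and 268, with 23 genes in place of 116 shared by both stages of the gate and 24 in place of 55 list medians of at least 1 in size. This setting changes the background model and adds an offset, and which of these moved the counts was not tested. Quantile normalization gave 754 for the E9.5 gate against other GFP-positive cells and 764 for the latter against GFP-negative cells, and the cause was not tested. Genes above background on both arrays numbered 360, 283, 380, 693, 430, 470 and 677, the E9.5 comparison of other GFP-positive with GFP-negative cells apart at 333, with 46 shared and 76 of the 160 named differences left, because bounds drop out. Without filter or bound there were 1229, 1420, 1165, 1938, 1964, 1522, 1599 and 3278, with 193 shared, where dim probes enter and no bound limits their folds, and these were not separated. At 2-fold there were 2667, 3490, 2624, 3310, 4394, 4238, 3925 and 6864, with 701 shared, since the threshold is lower. Median centring, the median of the probes of a gene and the unscaled table left all counts within 1.5 times. Of the named differences a single value changed sign, Ncam2 in other GFP-positive cells across stages, at -0.68 as the median of its probes against 5.56. Values of named differences moved by more than the spread in 157 of 160 cases with normexp, 105 with quantile normalization, 80 in the unscaled table, 50 without filter, 40 of 159 for the median of probes, 0 of 76 above background on both arrays and 0 with median centring. Of 264 list medians, 122, 93, 132, 49, 53, 80 and 0 moved in the same order of settings, and no called one reversed. For the named differences the 0 of 76 was fixed in advance, since that setting drops bounds and leaves all other values unchanged. Median centring and the unscaled table shift all differences of a comparison by the same amount, so their counts do not test single genes. No paired analysis was possible because all 7 populations carry replicate number 1 with 1 array each. For the same reason no replicate could be left out, and a slide block could not be run.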

Other observations

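Tests of the Y-linked genes and of the blood shares were chosen only after the results were seen, as were the genes in the next paragraph, while the count of bright transcripts lost at E11.5 was fixed before.

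Lin28a, Sall4, Krt8 and Krt18 stood at lower levels on both E11.5 arrays than on the 5 earlier ones. Lin28a, an RNA-binding protein of early embryonic cells, had levels of 5.60 and 4.29 at E8.5, 3.97, 4.21 and 3.68 at E9.5 and 0.46 and -1.50 at E11.5. Within a stage these are in the order gated, other GFP-positive and GFP-negative cells. Sall4, a factor of pluripotent cells, stood at 2.70 in GFP-positive cells of E8.5 and 1.67 in other GFP-positive cells of E9.5, and at E11.5 at -4.28, not well above background, and -3.34. The simple epithelial keratins Krt8 and Krt18 stood at 3.21 and 4.78 at E8.5 and at -3.35 and -0.84 in the gate at E11.5. Krt8 was already lower in the E9.5 gate than in the GFP-positive cells of E8.5. Dissected region changed along with stage, so stage and region cannot be told apart for these genes. Among genes of retinoid metabolism at E11.5, Dhrs3, a retinaldehyde reductase, and Aldh1a2, which makes retinoic acid, stood at 5.20 and 4.85 in the other GFP-positive cells against 3.29 and 3.61 in the gate, and Rdh10, which oxidises retinol, at 2.55 against 3.55. Rspo3, a secreted enhancer of Wnt signalling, was at 2.48 in the gate and 0.08 outside it at E11.5, and Bmper, a secreted modulator of Bmp signalling, at 1.58 and 1.83.

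Xist was not well above background on either E11.5 array, with signals of -6.6 and -6.93, against 2.26, 2.75, 2.7, 2.4 and 2.28 on the 5 earlier arrays (its probe in mm9 lies on chromosome X from 100662174 to 100662233). A general loss of bright transcripts is argued against, because of 3878 genes at a level of 2 or more on all 5 earlier arrays only 1, Xist itself, was lost on both. The E11.5 RNA may have come only or mostly from male embryos: 4 Y-linked genes, Ddx3y, Eif2s3y, Kdm5d and Uty, were higher in both E11.5 populations than in their E9.5 counterparts, in 8 of 8 differences, with a median of 1.24 above that of all genes. No other biological explanation was tested, and the sex of the embryos was not used here.

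The globins Hba-x, Hbb-bh1 and Hbb-y stood higher in the other GFP-positive than in the gated cells at E9.5, which could come from blood cells carried into that sort, although a gate on GFP should remove them. After the gated level was taken off they stood, in this order, at 0.454%, 0.824% and 0.87% of their GFP-negative levels of 6.68, 9.15 and 8.74, a range of 0.94 log2 units, as a single small share would need. Over a wider set of 8 genes (Alas2, Gata1, Hba-a1, Klf1, Slc4a1 and the same 3) the range was 5.4 units, with Klf1 at -2.26 and Hba-x at -7.66 log2 units from the GFP-negative level. Klf1 and Gata1 lay near the background in the other GFP-positive cells, at -3.3 and -3.77, and Alas2 was lower there than in the gate, at -1.57 against -0.07, so carry-over and expression in the sorted cells cannot be told apart here.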
